A study of Mus musculus with 3 samples.

How the data were processed

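RNA sequencing was done on LSK cells from the fetal liver of C57Bl/6 mouse embryos at E14.5. LSK cells carry no lineage markers and carry Sca1 and c-Kit on their surface, a fraction that holds blood stem cells and multipotent progenitors. DNMT3B7 is a truncated form of the DNA methyltransferase DNMT3B. Per the labels, 1 library came from wild-type (WT) embryos, 1 from embryos hemizygous for the DNMT3B7 transgene and 1 from homozygous embryos, so the libraries stand for 0, 1 and 2 transgenic alleles. Each library was made from the total RNA of cells pooled from 4 to 5 embryos, per the labels' protocols. Groups were taken from the genotype label alone.

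The values were deposited as FPKM, the number of fragments relative to transcript length and library depth, per gene, with a status for each estimate, per the file headers. TopHat2, Bowtie2, Cufflinks and the mouse genome build mm9 are named without versions, per the submitters' processing notes. The gene annotation, the strand setting and the mean fragment length are not given in the sources used here. The tables held neither read counts nor intervals, so the interval condition of the size rule was not used. Each table had 38230 rows and 38205 Ensembl gene identifiers, of which 36463 (95.4%) were found in the GENCODE mouse release M21 annotation of GRCm38. That annotation was used for gene types, transcript lengths, chromosomes and gene order. No base positions are given, because its build is not the one named for the files.

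The design had been fixed before the data were examined, and the values called for 2 departures from it. The first concerned the scale. The deposited FPKM of all genes other than small RNA genes summed to between 3583690000 and 4829750000 per library, far above what that unit allows. All 3 libraries were divided by the same factor, 4245.16 deposited FPKM, which brings the mean sum to 1000000. The pseudocount of 1, the minimum of 1 and the naming minimum of 5 were applied on that scale, called value below. A single factor leaves the ratios between libraries as deposited.

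The second departure concerned which genes were used. Many genes that all cells express were listed at or near 0, and high values were found in runs at the starts of some chromosomes. A break was therefore fitted on each chromosome by maximum likelihood, from the share of protein-coding genes with a mean deposited FPKM of at least 200000 before and after it. A segment was kept when it raised the log likelihood by at least 5. A set of constitutive genes (ribosomal, proteasome, splicing, respiratory chain and similar genes) and gene families that stand in long runs outside blood were left out of the fit. Genes before the breaks and mitochondrial genes are called in register, and comparisons were restricted to them. This rule was settled while looking at the values: fits at settings between 100000 and 1000000, with and without the gene families, and a 5-class fit were tried, and the setting was chosen from the genes beside the breaks, not from the comparisons. The constitutive genes had been seen under several of these rules, so their check is not fully independent.

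The depth was read from the low values. Among genes with a single annotated transcript of 1000 to 10000 bases, the values times the transcript length were whole multiples of 1 unit, within 0.05, for 72.1% of 767 low values in the WT library, 69.9% of 843 in the hemizygous library and 73.0% of 781 in the homozygous library, against 10% by chance. That unit was taken as 1 fragment, and fragments per gene were estimated with the median transcript length and an assumed fragment length of 200 bases. For short transcripts, mt-Atp8 and mt-Nd4l among them, the length less that of a fragment was held at a lower bound. The estimates came to about 3030000, 3010000 and 2310000 fragments on the listed genes other than small RNA genes, which leaves out reads not counted at a gene. They depend on the length taken: the longest transcript of each gene gave 5680000, 5940000 and 4800000, so the fragments and counting intervals given are approximate. A value of 1 for a transcript of 2000 bases stood for about 7.25 fragments in the WT library. From the estimated fragments came a counting standard error (SE) of each log2 ratio and its 95% interval, which cover counting error only and neither differences between embryos nor library making. The SE is that of the plain ratio of fragments, while the interval is centred on the log2 ratio of value + 1. For low genes the interval therefore lies nearer to 0 than that of the plain ratio. Counts of intervals that exclude 0 may be too low.

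No test between genotypes was possible with 1 library each, and no p-value is given. Libraries were compared by the log2 ratio of value + 1, which understates the change of low genes. A gene was measured in a comparison when its status was OK in both libraries and its value was at least 1 in at least 1 of them. It counted as higher or lower when its log2 ratio was at least 1 in size. Small RNA genes were left out. Named genes were, per comparison, the 10 with the largest log2 ratio in each direction among those past this rule with a value of at least 5 in either library, without predicted or unnamed gene models. Added to these were up to 4 measured members of each of 25 gene lists and a fixed set of DNA methyltransferase, surface marker, hormone receptor and sex-linked genes. Where other genes are named, the text says that they were chosen after their values were seen. Libraries that differ by counting error alone were simulated 100 times from the mean values with Poisson counts of the fragments estimated with the median transcript length. The order by number of transgenic alleles was set beside 100 further draws, in which genes were chosen by the same rule. Stretches of 50 bases that a named gene's transcripts share with other genes, and overlaps of exons, were taken from the annotated transcripts.

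The segment fit, the fragment unit and the size rule were tested on simulated data with known answers. Of 10 simulated breaks, 10 were found, with a median error of 1 gene and a largest error of 8 genes. The simulated values followed the model of the fit. Segments as short as the 10 fitted genes on chromosome 12, where Dnmt3a lies, or as long as the 520 on chromosome 16 were not simulated. The simulated fragment unit was recovered within 0.0206%, with 100% of the low values whole. The simulation used the same lengths as the recovery, so it could not test the lengths taken. For the comparison of the homozygous with the WT library, the size rule recovered 91.0% of 200 genes changed 3-fold per draw, 3.67% of genes changed 1.5-fold, a change below the rule by construction, and called 2.76% of the unchanged genes drawn beside the 3-fold changes. For hemizygous versus WT the 3-fold recovery was 91.4%, and for homozygous versus hemizygous 91.8%.

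Alternatives fixed before the data were examined were another pseudocount, other minimum values, a median-ratio and a sum scaling, other size thresholds, keeping small RNA genes, leaving out sex-linked and globin genes, and summing rows that share a symbol. The last was run on rows that share an Ensembl gene identifier instead. The sum used for scaling includes the mitochondrial mRNAs, so a difference in them shifts the ratios of all other genes under sum scaling. Alternatives added afterwards were a counting interval that must exclude 0, fragments estimated with the longest transcript, protein-coding genes only, other settings of the segment fit, values not rescaled, and all rows. The design exactly as written corresponds to all rows without rescaling. The scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.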

Results

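Gene expression was measured by RNA sequencing in LSK cells, the stem and progenitor fraction of blood cells, sorted from the fetal liver of mouse embryos at E14.5. Embryos were WT, hemizygous or homozygous for a transgene encoding DNMT3B7, a truncated form of the de novo DNA methyltransferase DNMT3B. Each genotype was represented by 1 library from a pool of 4 to 5 embryos, so none of the differences given here has a replicate check, and each compares libraries rather than genotypes. The low values implied about 3030000 fragments on the listed genes other than small RNA genes in the WT library, 3010000 in the hemizygous library and 2310000 in the homozygous library, with the median transcript length of each gene. Reads not counted at a listed gene are outside these totals. Of the fragments on the genes compared, the mRNAs of the mitochondrial genome took 64.4% (95% Wilson interval 64.3 to 64.5) in the WT library, 60.6% (60.6 to 60.7) in the hemizygous library and 51.7% (51.7 to 51.8) in the homozygous library. These intervals cover counting error only, not the lengths taken. For mt-Atp8 and mt-Nd4l the length used was the lower bound set for short transcripts. The genes compared are 4.36% of the gene identifiers other than small RNA genes, so these are not shares of the whole library. With the longest transcript of each gene the totals were 5680000, 5940000 and 4800000 and the shares 41.9%, 37.3% and 29.8%, in the same order of libraries. All values below are rescaled FPKM.

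Values could be read for part of the genome. Ly6a and Kit, which encode the Sca1 and c-Kit proteins used for the sort, were listed at 0 in the WT library, and Eef1a1, a translation elongation factor needed by all cells, was listed at 0 in all 3 libraries. Such genes lay outside 10 chromosome segments that held runs of high values. The longest covered 520 of the 553 genes fitted on chromosome 16, up to Morc3, and the next were 135 of 609 genes on chromosome 19, up to Rasgrp2, and 101 of 854 on chromosome 8, up to Agpat5. Of the constitutive genes left out of that fit, 13 of 13 before the breaks were high, with a median value of 698, against 14 of 250 outside the segments, where 111 were listed at 0 in all 3 libraries and the median was 0.10. Of these, 4 of 87 were high after a break and 10 of 163 on chromosomes without a fitted break. The comparisons therefore cover 1442 genes, 826 of them on chromosome 16 and 13 on the mitochondrial genome, of which 963 reached a value of 1 in a library. Cfl1, the actin-severing protein cofilin, named after its values were seen, was the most abundant nuclear gene among them, with 9022 in the hemizygous and 9671 in the homozygous library.

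**Figure D1:**
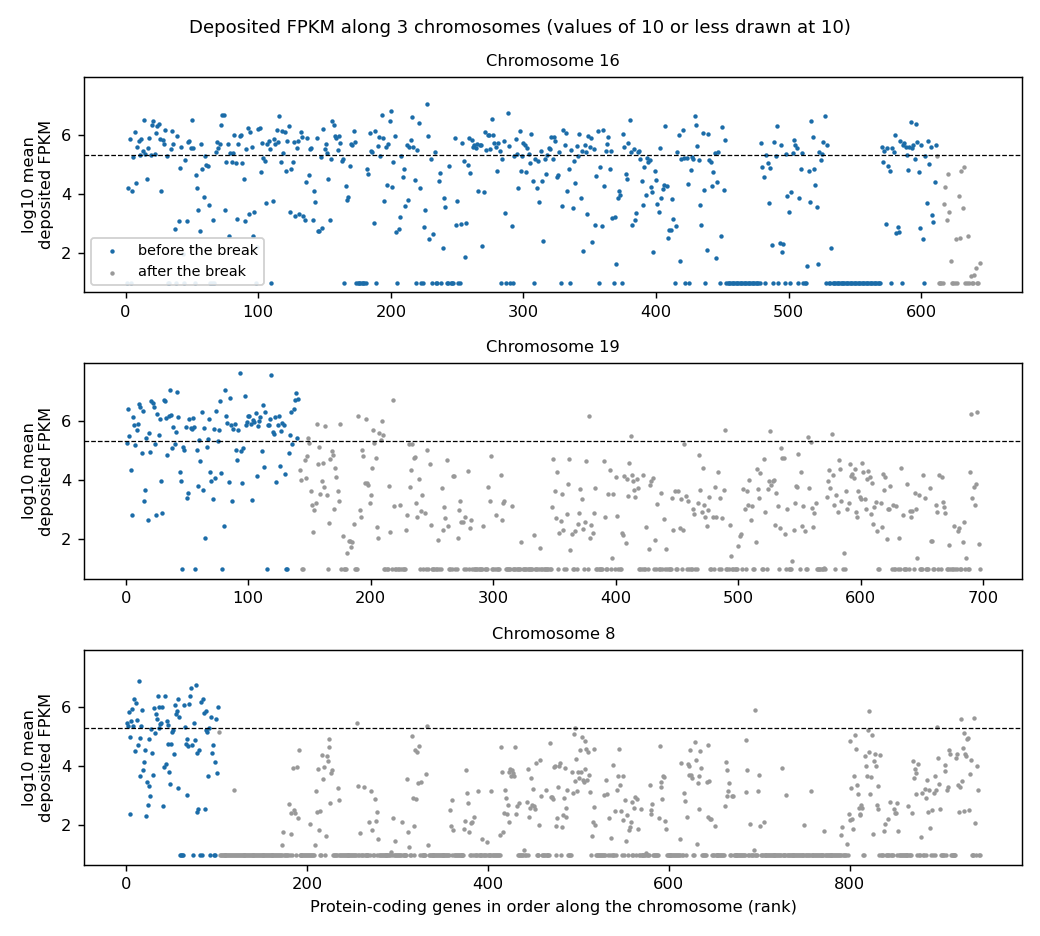
Mean deposited FPKM over the 3 libraries (log10 scale; the dashed line marks 200000) of protein-coding genes in order along chromosomes 16, 19 and 8, with genes before the fitted break in blue and genes after it in grey. High values run along nearly all of chromosome 16 and the starts of chromosomes 19 and 8, and over all chromosomes 44.3% of the genes fitted before the breaks were high against 2.97% of the other genes fitted.

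The transgene encodes a form of a DNA methyltransferase, so the methyltransferase genes were looked at first. Dnmt3a, which encodes the other de novo DNA methyltransferase, was on chromosome 12 before the break and had values of 603 in the WT, 698 in the hemizygous and 683 in the homozygous library. Its log2 ratio to WT was 0.21 ± 0.05 (counting SE) in the hemizygous and 0.18 ± 0.05 in the homozygous library. Under sum scaling they were 0.37 and 0.61, short of the size rule. Dnmt3b, Dnmt1 and Dnmt3l lay outside the segments, as did Cd34, Ptprc, Esr1, Esr2, Pgr, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Expression of the transgene itself was not analysed here, so the labels were not checked on it, and the sex of the pools was not described.

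The comparison of the homozygous with the WT library asked what expression differs when both alleles carry the transgene. Genes of the surrogate light chain, which pairs with the immunoglobulin heavy chain in the pre-B cell receptor, were lower in the homozygous library. Igll1 (ENSMUSG00000075370), which encodes the lambda5 chain, had values of 236 in the WT and 95.5 in the homozygous library, Vpreb1 (ENSMUSG00000059305) 174 and 57.0, and Vpreb2 (ENSMUSG00000059280) 107 and 39.7. The log2 ratios were -1.30 for Igll1 (95% counting interval -1.45 to -1.14), -1.59 for Vpreb1 (-1.95 to -1.24) and -1.41 for Vpreb2 (-1.77 to -1.05). St6gal1 (ENSMUSG00000022885), the sialyltransferase that adds alpha-2,6-linked sialic acid to glycoproteins, was lower as well, with 48.2 in the WT and 19.4 in the homozygous library and a log2 ratio of -1.27 ± 0.14 (counting SE). All 4 genes lie on chromosome 16.

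Other named genes were lower in the homozygous library as well. Rpl39l, a paralog of the ribosomal protein gene Rpl39, was at 16.4 in the WT and 4.47 in the homozygous library, a log2 ratio of -1.67 (-2.78 to -0.56). Mrpl39, a protein of the mitochondrial ribosome, was at 20.01 and 6.29, with a log2 ratio of -1.53 (-2.12 to -0.93). Popdc2, a cyclic AMP-binding membrane protein known from heart muscle, was at 27.3 and 8.31 (-1.61, interval -2.32 to -0.89), and Fabp4, the fatty acid-binding protein of fat cells and macrophages, at 11.4 and 4.18 (-1.26, interval -1.79 to -0.73). Lmln, a metallopeptidase, had the smallest difference of them, at 14.7 and 6.73 (-1.03, interval -1.91 to -0.14), and lay at -0.99 under median-ratio scaling.

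Named genes that were higher in the homozygous library had low or moderate values. Efemp2, the extracellular matrix protein fibulin-4 needed for elastic fibres, was at 5.10 in the WT and 15.5 in the homozygous library, a log2 ratio of 1.43 (95% counting interval 0.53 to 2.33). Slc15a2, a proton-coupled peptide transporter, was at 17.7 and 38.5 (1.08, interval 0.59 to 1.56), and Ccdc116, a coiled-coil protein, at 9.17 and 19.4 (1.00, interval 0.59 to 1.42). Rhod, a small GTPase of endosomes, was at 2.68 and 7.66 (1.23, interval 0.25 to 2.22). For Apod, the lipocalin apolipoprotein D, and Pigz, a mannosyltransferase of the GPI anchor pathway, the log2 ratios of 1.46 and 1.43 rested on an estimated 2.96 and 1.65 fragments in the WT library. Their counting intervals reached below 0, from -0.39 to 3.31 and from -1.05 to 3.90. These are centred on the ratio of value + 1, while the plain ratio was 3.93-fold for both genes. They do not decide whether the plain ratio of Apod lay beyond counting error.

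**Figure D2:**
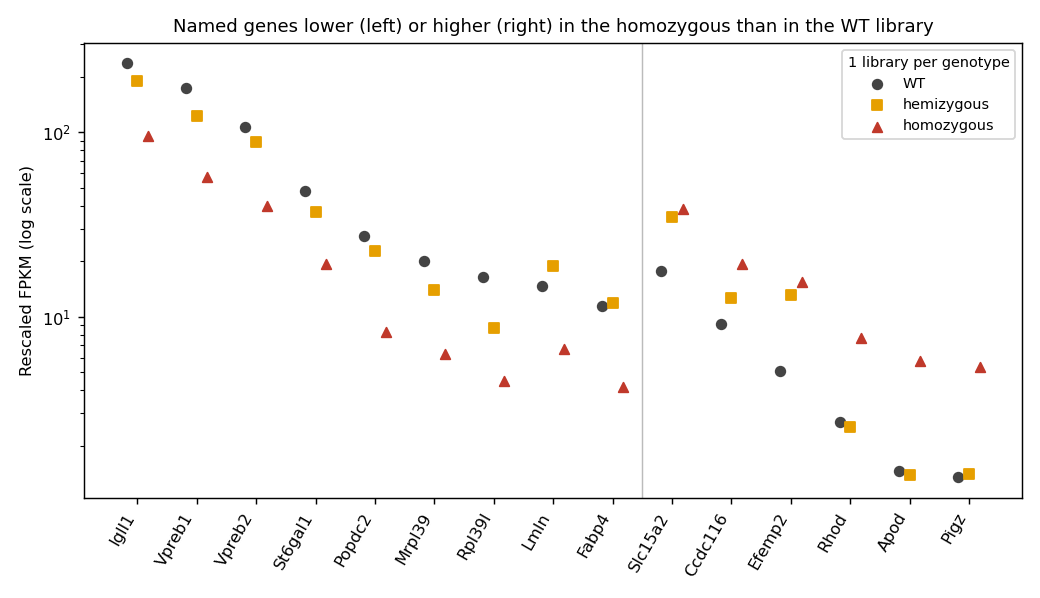
Rescaled FPKM (log scale) of the 15 named genes past the size rule between the homozygous and the WT library, with 1 point per library. For Igll1, Vpreb1 and Vpreb2 the homozygous library lies lowest (95.5, 57.0 and 39.7) and the hemizygous library lies between the others (190.0, 122 and 88.3).

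Of 946 genes measured in this comparison, 21 were higher and 21 lower in the homozygous library, and 87.6% lay within 1.5-fold. Simulated libraries that differed by counting error alone gave 24.0 such genes on average and at most 34 in 100 draws. Among genes with a value of at least 5 in either library the count was 22, 10 higher and 12 lower, against a simulated mean of 5.56 and a highest of 11. Centred on the ratio of value + 1, the counting interval excluded 0 for 5 of the higher genes, Efemp2, Slc15a2, Ccdc116, Rhod and A330021E22Rik (the last named after its value was seen), and for 11 of the lower genes. Median-ratio scaling moved the median log2 ratio by 0.03 and gave 22 higher and 19 lower. Scaling each library to the same sum of values moved it by 0.42 and changed the split to 46 higher and 10 lower. That sum includes the 13 mitochondrial mRNAs, the highest of which, mt-Atp8, was at 173767 in the WT and 107359 in the homozygous library. Their lower values in the homozygous library lift the ratios of nuclear genes under sum scaling. Under that scaling Igll1 (-0.87), Vpreb2 (-0.99), St6gal1 (-0.85), Fabp4 (-0.89) and Lmln (-0.64) no longer passed the size rule. The homozygous library was also the one with the lowest mitochondrial share of the fragments on the genes compared (51.7%) and the highest values of the vessel wall collagen genes Col4a1 and Col4a2.

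Reads of some of these genes may not be told apart from those of neighbours or paralogs, since the strand setting was not given. Of the 50-base stretches of the Vpreb1 transcripts, 18.8% also occur in Vpreb2, and of those of Vpreb2 32.8% occur in Vpreb1. Igll1, St6gal1, Rpl39l, Mrpl39, Fabp4, Efemp2 and Rhod shared 0% with other genes. Exons overlap on the opposite strand between Vpreb1 and Top3b, St6gal1 and BC106179, Ccdc116 and Ydjc, Efemp2 and Mus81, and Rhod and A930001C03Rik, and on the same strand between Popdc2 and Gm21987 and between Pigz and Gm49731. A930001C03Rik, named after its values were seen, was past the size rule in the same direction as Rhod, with a log2 ratio of 1.09 for homozygous versus WT.

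The gene lists fixed for blood lineages and pathways were covered thinly, with 34 of 807 members in register, so they are given as values and no list had the 5 measured members needed for a percentile. In the lymphoid list all 3 measured members, Igll1, Vpreb1 and Vpreb2, passed the size rule as lower in the homozygous library, and no measured member of the other lists passed it in this comparison in either direction. The plain ratios of Mmp8 (0.47) and Hey1 (0.40) were falls of more than 2-fold, and the pseudocount of 1 kept both short of the rule. They rested on an estimated 30.5 and 7.76 fragments in the WT library and 13.7 and 2.94 in the homozygous library. Under sum scaling Vpreb1 (-1.17) still passed as lower, Igll1 (-0.87) and Vpreb2 (-0.99) did not, and Col4a1, Col4a2 and Gp5 of other lists passed as higher. Of the stem cell regulators, Runx1, the transcription factor needed for the emergence of blood stem cells, was at 152 in the WT, 153 in the hemizygous and 132 in the homozygous library. Its log2 ratio of -0.19 for homozygous versus WT turned to 0.23 under sum scaling.

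Erythroid and megakaryocyte genes did not pass the rule. Tfrc, the transferrin receptor, was at 1280 in the WT, 1414 in the hemizygous and 1013 in the homozygous library. Cpox, an enzyme of haem synthesis, was at 442, 442 and 409 in the same order. The carbonic anhydrase genes had values of 64.7, 65.0 and 76.7 for Car1 and 2200, 2091 and 1786 for Car2. The log2 ratio of Tfrc for homozygous versus WT, -0.34, turned to 0.09 under sum scaling. Gp5, a subunit of the platelet receptor for von Willebrand factor, was at 16.5, 17.7 and 30.1, with a log2 ratio of 0.83 ± 0.16 (counting SE) for homozygous versus WT. Gp1bb, of the same receptor, was at 5.502, 3.09 and 4.76 and shared 90.6% of its stretches with other genes, chiefly Sept5, and Mylk stood near 4 in each library (3.79, 3.53 and 3.80).

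Among myeloid genes, Cebpd, a transcription factor of granulocytes and monocytes, was at 42.2 in the WT, 36.1 in the hemizygous and 34.1 in the homozygous library, and Mmp8, a neutrophil collagenase, at 3.41, 3.64 and 1.61. Markers of cells outside the gate were measured for liver parenchyma and vessel wall. Ahsg, the hepatocyte protein fetuin-A, was at 3.70, 3.49 and 3.67 in the 3 libraries. The basement membrane collagen genes Col4a1 and Col4a2, which are neighbours on chromosome 8 and overlap on opposite strands, were at 25.5, 31.7 and 45.2 and at 27.1, 36.4 and 54.1, with log2 ratios for homozygous versus WT of 0.80 ± 0.27 and 0.97 ± 0.20 (counting SE). Under sum scaling both ratios (1.22 and 1.39) and that of Gp5 (1.24) passed the size rule, and Col4a2 reached it under median-ratio scaling (1.00).

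Hormone receptor, DNA replication, interferon and stress genes named here lay below the rule in all 3 comparisons. Nrip1, a corepressor of oestrogen and other nuclear receptors, was at 80.2 in the WT, 119 in the hemizygous and 106 in the homozygous library, with log2 ratios to WT of 0.56 ± 0.08 and 0.40 ± 0.08 (counting SE), which under sum scaling were 0.72 and 0.83, in the other order. Insr, the insulin receptor, was at 64.0, 74.4 and 63.2. Of the DNA replication genes, Mcm4 was at 408, 402 and 390, Cdc45 at 19.6, 19.22 and 25.2, and Rfc4 at 222, 185 and 216. The interferon-induced genes Rtp4 (69.5, 41.8 and 71.8) and Parp14 (44.9, 46.6 and 49.9) and the early response gene Klf6 (61.6, 62.4 and 47.2) stayed within the rule, as did the glycolysis gene Pfkp (35.7, 30.2 and 27.5). Under sum scaling Rtp4 passed it between the homozygous and the hemizygous library (1.03). Hey1, a Notch target, was at 2.60, 1.40 and 1.03. The nuclear respiratory chain genes Atp5j, Atp5o, Ndufs8 and Ndufv1 had log2 ratios of -0.04, -0.19, 0.10 and -0.06 for homozygous versus WT. Dppa2 and Dppa4, germline genes silenced by methylation in somatic cells, did not reach a value of 1 in any library. No member was in register for the lists of gate markers, HOX clusters, mast cells, macrophages, imprinted genes, mitosis, p53 targets and sex of the embryos.

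The comparison of the hemizygous with the WT library asked what differs with a single transgenic allele. Efemp2 was the only gene that met the naming rule, with values of 5.10 in the WT and 13.1 in the hemizygous library and a log2 ratio of 1.21 (95% counting interval 0.31 to 2.12). The surrogate light chain genes did not pass the rule here. Igll1 was at 190.0 in the hemizygous library (-0.31, interval -0.43 to -0.19), Vpreb1 at 122 (-0.51, interval -0.77 to -0.25) and Vpreb2 at 88.3 (-0.28, interval -0.54 to -0.01). Under sum scaling the ratios were -0.15, -0.35 and -0.12, the last within its counting error of 0. Slc15a2 came close, with 34.7 in the hemizygous library and a log2 ratio of 0.93 (0.44 to 1.42).

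Of 945 genes measured, 18 were higher and 9 lower in the hemizygous library, and 92.0% lay within 1.5-fold. Simulated counting error alone, with fragments from the median transcript length, gave 22.8 on average and at most 35, and the observed 27 lay within that range. The longest transcript, which gives more fragments, was not simulated. At values of at least 5 the count was 8 against a simulated mean of 5.27 and a highest of 10. Unnamed gene models made up 13 of the 18 higher and 4 of the 9 lower genes. Under sum scaling, which moved the median by 0.16, the split was 22 higher and 6 lower, and Slc15a2 passed the rule (1.08).

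The comparison of the homozygous with the hemizygous library asked what differs between 1 and 2 transgenic alleles. Vpreb1 and Vpreb2 were lower in the homozygous library, with log2 ratios of -1.09 (95% counting interval -1.45 to -0.72) and -1.13 (-1.50 to -0.77), and Igll1 lay just inside the rule at -0.98 (-1.14 to -0.83). Hes1, a transcriptional repressor induced by Notch signalling, was at 33.0 in the WT, 41.5 in the hemizygous and 18.9 in the homozygous library, a log2 ratio of -1.09 (-1.78 to -0.41) between the transgenic libraries. Popdc2 (-1.35), Lmln (-1.36), Fabp4 (-1.31) and Mrpl39 (-1.05) were lower too; Mrpl39 lay just short of the rule under median-ratio scaling (-0.999). Rhod (1.29), Apod (1.501) and Pigz (1.39) were higher. For Apod and Pigz the counting interval, centred on the ratio of value + 1, included 0, while the plain ratios were 4.15-fold and 3.76-fold.

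Of 953 genes measured, 16 were higher and 27 lower in the homozygous library. Simulated counting error alone gave 24.5 on average and at most 35. At values of at least 5 the count was 19, 5 higher and 14 lower, against a simulated mean of 5.58 and a highest of 10. Sum scaling moved the median by 0.27 and gave 30 higher and 15 lower, and under it Vpreb1 (-0.82), Vpreb2 (-0.87), Hes1 (-0.84) and Mrpl39 (-0.81) no longer passed.

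The libraries also allowed the order by number of transgenic alleles to be read. Of the 42 genes past the rule between the homozygous and the WT library, 27 (64.3%) had their hemizygous value between both. The genes were chosen by the gap between these 2 libraries, which alone favours a middle value: of genes past the same rule in libraries simulated with counting error alone, 56.4% lay between. Among the lower genes this held for 17 of 21 (simulated 57.1%), Igll1, Vpreb1, Vpreb2, St6gal1, Mrpl39, Rpl39l and Popdc2 included, and among the higher genes for 10 of 21 (simulated 55.7%), Efemp2, Slc15a2 and Ccdc116 included. Fabp4 and Lmln had their highest value in the hemizygous library. At values of at least 5 the counts were 10 of 12 lower genes (simulated 70.9%) and 6 of 10 higher genes (simulated 67.4%). The simulation holds no true differences, so these counts do not show an order by dose.

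Both transgenic libraries were compared with the same WT library, which alone pushes their ratios together. Across the 930 genes measured in both, the log2 ratios to WT had a Pearson r of 0.52 and a Spearman rank correlation of 0.51, while libraries simulated with counting error alone gave 0.54 and 0.46 on average. Genes are not independent replicates, and no p-value is given. The covariance was 0.0747 against a simulated 0.04997, a difference of 0.0248, with simulated values of up to 0.0902. At a mean value of at least 5 it was 0.0538 in 781 genes against a simulated mean of 0.0172 and a highest of 0.0271, while the Pearson r at that minimum, 0.56, lay within the simulated range (mean 0.497, highest 0.658). The Spearman correlation at that minimum, 0.575, lay above the simulated range (mean 0.456, highest 0.543). Efemp2 was among 5 genes higher in both transgenic libraries, where independent lists would share 0.181 and the simulation gave 4.18. Lower in both were 3 genes, with 0.203 for independent lists and 3.73 simulated, and 1 gene had opposite directions. Named after their values were seen, the others higher in both were the gene models Gm15696, Gm16180, Gm21747 and Gm15835, those lower in both Gm20695, Gm15351 and Gm15798, and the opposite one Gm15976. Part of any excess may come from the shared WT library, which could not be split.

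**Figure D3:**
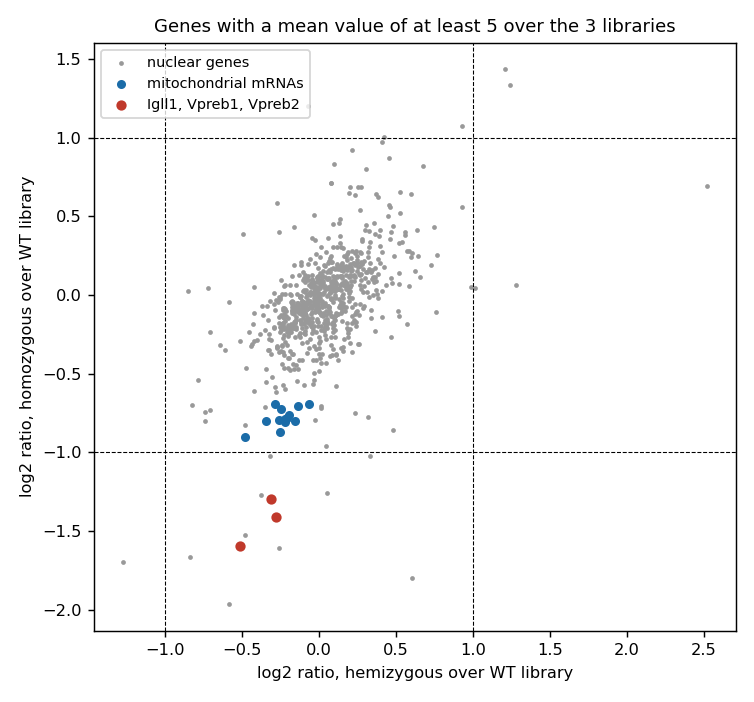
Log2 ratio to the WT library in the hemizygous library (x axis) and in the homozygous library (y axis) for genes in register with a mean value of at least 5, with the size rule as dashed lines. Igll1, Vpreb1 and Vpreb2 lie at -0.31, -0.51 and -0.28 on the x axis and at -1.30, -1.59 and -1.41 on the y axis, and the 13 mitochondrial mRNAs lie below 0 on both axes. Under sum scaling Igll1, Vpreb1 and Vpreb2 lie at -0.15, -0.35 and -0.12 on the x axis and at -0.87, -1.17 and -0.99 on the y axis, and the mitochondrial medians at -0.06 and -0.36, with 3 mRNAs above 0 on the x axis and 0 on the y axis. The mitochondrial mRNAs are part of that sum, which draws their ratios towards 0 by construction.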

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

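The counting interval, the longest transcript, the restriction to protein-coding genes, other segment settings, unrescaled values and all rows were chosen after the results were seen; the other alternatives were fixed before the data were examined. Of 91 alternatives to the counts of genes, the dose order, the shared genes, their correlation and the list members, 35 stayed within the bound (1.5 times for counts) and 56 did not. Another 21 could not change a result and are not counted: no sex-linked or globin gene was in register, the files held no intervals to leave out, a gene below the minimum cannot reach the size rule, and the correlation does not use the calls. Of 72 alternatives for 23 named genes and the mitochondrial median, 61 moved within the 95% counting interval of the main value (for the mitochondrial median, the SD of its 13 mRNAs), 11 by more, and 0 called values changed sign. Counts below are given in the order hemizygous versus WT, homozygous versus WT, homozygous versus hemizygous. They stayed within 1.5 times of 27, 42 and 43 under median-ratio scaling (26, 41, 42), sum scaling (28, 56, 45), and segments fitted at 100000 (1472 genes in register) or at 1000000 (24, 37 and 35 calls among 1174 genes). Sum scaling kept the totals but not the genes. Only 24, 31 and 31 of the 27, 42 and 43 genes were called again, and 22, 46 and 30 were higher instead of 18, 21 and 16. The 11 larger moves of single values above all came under sum scaling. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out.

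With a pseudocount of 0.1 the calls were 44, 60 and 73, with 14 genes shared by both comparisons with WT (8 in the report) and 5 list members (3 in the report). A minimum of 5 gave 8, 22 and 19, with 16 in dose order and 3 shared. A 1.5-fold threshold gave 76, 117 and 109, with 77 in dose order and 26 shared; a 4-fold threshold gave 4 (Gm21747, Gm15738, Gm15799, Gm15835), 2 (Gm16180, Gm15835) and 2 (Gm15799, Gm15976), with 1 in dose order and 1 shared, genes named after their values were seen. With small RNA genes kept there were 59, 67 and 72, 22 shared and a correlation of 0.82. Requiring a counting interval without 0 left 5 (Efemp2 and, named after their values were seen, Gm10217, Gm6293, Gm20695 and Cd248), 16 and 11, with 13 in dose order and 2 shared; with fragments from the longest transcript it left 10, 19 and 18, with 15 in dose order and 2 shared, and protein-coding genes alone gave 10, 24 and 18 with 2 shared.

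Without rescaling, the pseudocount and minimum lose their weight, and genes in register gave 155, 169 and 180 calls, 66 in dose order, 70 shared and a correlation of 0.67. All rows on the rescaled values gave 1128, 980 and 1171, 500 in dose order, 351 shared and a correlation of 0.64. All rows without rescaling, the design as first written, gave 6672, 6070 and 6556, with 2149 in dose order, 3124 shared and a correlation of 0.72. The looser and stricter settings change how many genes can pass by construction; the cause of other differences was not tested.

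Random lists without matching were not run, because no list had 5 measured members, and scaled values of Dnmt3b and of sex-linked genes were not run, because these lay outside the segments. Depth limits low genes most: a value of 1 for a transcript of 2000 bases stands for 7.25 fragments in the WT library, and of the 24.0 genes per draw that counting error alone put past the size rule for homozygous versus WT, 5.56 had a value of at least 5.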

Other observations

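The tests in this part were chosen after the results were seen, except that the scalings were fixed before. The genes of its opening paragraphs were also chosen after their values were seen, except Rtp4, which was in a list fixed before, as were the surrogate light chain and nuclear respiratory chain genes. Some genes short of the size rule had ratios well beyond counting error. Cers4, a ceramide synthase, was at 43.2 in the WT, 69.6 in the hemizygous and 77.1 in the homozygous library, a log2 ratio to WT of 0.82 ± 0.09 (counting SE) in the homozygous library. Adcy3, an adenylyl cyclase, was at 21.1, 31.0 and 33.9 (0.66 ± 0.10), Dnase1, a secreted nuclease, at 52.6, 62.9 and 85.0 (0.68 ± 0.15), and Cdc42bpg, a kinase bound by the GTPase Cdc42, at 32.3, 34.1 and 53.4 (0.71 ± 0.09). Dexi (57.8, 41.2 and 32.1; -0.83 ± 0.15) and Pygm, the muscle form of glycogen phosphorylase (78.6, 61.5 and 47.6; -0.71 ± 0.11), had their lowest values in the homozygous library. Tmem134, a membrane protein gene, was at 697 in the WT and at 418 and 416 in the transgenic libraries. Under sum scaling Cers4 (1.24), Adcy3 (1.07), Dnase1 (1.11) and Cdc42bpg (1.13) passed the size rule for homozygous versus WT, while Dexi (-0.41), Pygm (-0.29) and Tmem134 (-0.31) lay nearer to 0.

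Other genes had their value most distant from WT in the hemizygous library, under sum scaling too. Vasn, a membrane protein that binds TGF-beta, was at 35.0 in the WT, 67.6 in the hemizygous and 52.1 in the homozygous library, with log2 ratios to WT of 0.93 ± 0.13 (counting SE) and 0.56 ± 0.13. Under sum scaling these were 1.08, past the size rule, and 0.98. Ccl25, a chemokine that attracts thymic progenitors, was at 35.4, 60.9 and 42.4. The interferon-induced gene Rtp4 was lowest in the hemizygous library (69.5, 41.8 and 71.8).

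Many genes used by all cells were listed at or near 0 in all 3 libraries outside the segments described above. Failed estimates are argued against by the status of the rows at 0, which was OK for at least 98.9% of them in each library, and low depth by the constitutive genes before the breaks, the lowest of which had an estimated 376 fragments. On the chromosomes with a break, 4.6% of the constitutive genes after it were high, against 100% before it, and on chromosomes without a fitted break 6.13% were. A candidate explanation is that reads aligned to one genome build were counted at gene positions of a later one, since a shift in position would start at a point on a chromosome and last to its end. No biological explanation was tested, the later build was not identified, and where no break was fitted the start of a shift was not seen.

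The surrogate light chain genes were lower in the homozygous library, and scaling is argued against as the whole cause, since the smallest of the 3 falls in any scaling was -0.87 (Igll1, sum scaling). Reads moved between the paralogs Vpreb1 and Vpreb2 are argued against by their sum, which had a log2 ratio of -1.53, and by Igll1, which shared 0% of its stretches. The 20 measured genes nearest in order to Igll1 on chromosome 16, with its neighbour Vpreb1 left out, had a median of 0.015 (from -0.38 to 1.00, the last for Ccdc116). Fewer B lineage cells in the homozygous pool and lower expression per cell cannot be told apart, because 0 other members of the lymphoid list were measured; the sort removed cells with lineage markers. An effect of the transgene was not tested, since each genotype had 1 pool.

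The 13 mitochondrial mRNAs were lower in both transgenic libraries than in WT, with median log2 ratios of -0.22 in the hemizygous and -0.79 in the homozygous library and 0 past the size rule. Under sum scaling the medians were -0.06, with 3 members above 0, and -0.36. These mRNAs are part of that sum, so sum scaling draws their ratios towards 0 by construction. For homozygous versus WT, 0 of 10000 random lists of 13 genes from the 100 most abundant nuclear genes had a median as low, and for hemizygous versus WT 9 did. A single scaling factor moves all genes alike. For homozygous versus WT the gap to the median of these 100 genes was -0.72, against an SD of 0.18 among them, which argues against such a factor as the whole cause. For hemizygous versus WT the gap was -0.14, within the SD of 0.21, and 1 of the 13 lay above that median. In both comparisons the 13 mRNAs moved together (SD 0.06 for homozygous and 0.10 for hemizygous versus WT), unlike the genes of a random list. The counts of 0 and 9 lists therefore do not decide. Over the 768 nuclear genes with a mean value of at least 5 the gaps were -0.75 for homozygous and -0.24 for hemizygous versus WT. Scaling cannot say whether the mitochondrial mRNAs were lower or the nuclear ones higher. For homozygous versus WT a fall of the whole respiratory chain is argued against by a median of -0.051, on the scale as deposited, in 4 nuclear respiratory chain genes. These were the only measured members of the 49 in that list, so the rest of the chain was not covered. RNA quality or library making may differ between pools and cannot be told apart from genotype with 1 library per genotype.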
